A study of Rattus norvegicus with 12 samples.

How the data were processed

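RNA of the whole hippocampus was profiled on 12 arrays from male rats of postnatal day 14. The samples belonged to the bred High Responder line (bHR, 6 arrays) and the bred Low Responder line (bLR, 6 arrays) in generation 15 of the breeding programme. Per the labels' protocols, the hippocampus was dissected on ice and frozen, total RNA was extracted with TRIzol and column purified, and each RNA was split into aliquots for different array platforms. Only the Affymetrix RAE230A aliquots were analysed here. This array carries short oligonucleotide probes, several of which are summarised into 1 value per probe set. The description of 1 bLR array, replicate 3, says that it failed quality control. That array was left out of the comparison before the data were examined and was used only as an alternative.

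The deposited table holds log2 values, and the submitters' processing notes name RMA and affy 1.54.0 without further detail. RMA subtracts background, equalises the distribution of values across arrays and summarises the probes of a set by median polish. No header states the log base, and log2 was inferred from the range of the values and from RMA. The row names are Entrez gene numbers, so a custom chip definition with 1 probe set per gene was used, and which version it was is not given in the sources used here. The table gives no detection call and no background value, so no probe set could be called absent. Equalised distributions also remove any difference between arrays in total signal. The number of arrays limits the precision of every value below.

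The table has 10019 probe sets, of which 57 are Affymetrix control sets, and the remaining 9962 were tested. Symbols came from the Entrez number through a RefSeq gene table for 9831 probe sets, and 9848 were named by that table or by the platform annotation. The other 114 were left unnamed. Both tables gave a symbol for 9498 probe sets, and the symbol was the same for 9075 of them (95.55%). No 2 probe sets shared a symbol. The sources name no genome build, so no coordinates are given.

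The deposited values were used as they stand. The lines were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as bHR minus bLR, with 6 bHR and 5 bLR arrays and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 9962 probe sets, and the threshold was an adjusted p of 0.05. Nothing in the labels says how the rats were related or whether RNA was extracted in batches, so p-values measure the spread between these samples.

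Gene lists were fixed before the data were examined. They comprised 17 lists of cell type or region markers and 23 lists of pathways, receptor systems and genes that earlier or later work on these lines had named, each with at least 5 measured genes. Later work pooled these same arrays, so the list of named candidates is not independent evidence. Lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation, fry of limma and an exact permutation of the line labels over all 462 splits of the 11 arrays were run beside it. A further 3 lists had fewer than 5 measured genes (Cajal-Retzius cells 4, ribosomal proteins 4, sex check 1) and were not tested as sets. None of their members passed an unadjusted p of 0.05.

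The rule for named genes was also fixed beforehand. Because fewer than 10 genes passed the threshold, the 10 higher and the 10 lower in bHR with the smallest unadjusted p were named, and all of them were above the threshold. To these were added 10 candidate genes and up to 4 members of each list with the smallest p. Of the 10 candidates, 4 (Mki67, Sp3, Tmem144 and Acad11) were not matched to a probe set here.

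Whether the values belong to the row names was checked after some levels had been seen. Mean levels over the 11 arrays were turned into percentiles among the 9962 probe sets. Families used by nearly every cell or by neurons, chosen by symbol prefix, were set beside families best known from other organs, with a bootstrap 95% interval of the difference. Different probe sets differ in affinity and background, so these percentiles only describe the table. The median percentile of each planned list was also set among 10000 random lists of its size. For the control sets, the share of the variance of level that lay between transcripts was compared with 100000 shufflings of the names. As a check that does not use levels, residuals from the group means were correlated between pairs of control sets over the 11 arrays. The mean over pairs of the same transcript (54 sets of 12 transcripts) was compared with 100000 shufflings of the names in a 1-sided permutation test.

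The procedures were tested on simulated data. Each simulation used the arrays' own spread and planted 200 changed probe sets. In these, limma called 33.13% of probe sets changed by log2 0.25, 96.42% of those changed by 0.5 and all 660 changed by 1. It also called 79 of 97370 unchanged ones. The adjusted threshold is stricter where fewer probe sets differ. These shares therefore do not give the power for a few changed probe sets, which would be lower. Camera called a list of 25 members shifted by 0.15 in 10 of 10 simulations and 0 of 400 random lists. The simulated probe sets varied independently, whereas the estimated correlation within a real list reached 0.188 (CA1 pyramidal neurons, 7 probe sets). Power and false calls may therefore differ for the real lists. The covariation test found shared changes in 20 of 20 simulations that held them, and in 2 of 20 that did not. The shared changes were planted as large as the noise, so the power for weaker ones is not known.

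The alternatives fixed beforehand were the failed array included, with and without array weights; array weights on the 11 arrays; a variance trend with robust estimation; the dimmest 30% of probe sets left out; repeated quantile normalization; median centring; the sample number as a block; a residual component or a marker list mean (choroid plexus, blood or oligodendrocyte) as a covariate; other thresholds; and each array left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the checks of the row names and the plots.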

Results

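The series addressed how hippocampal gene expression differs early in life between rats bred for high and for low locomotor response to a new environment. The bHR rats descend from animals that explored much and the bLR rats from animals that explored little. The comparison used 6 bHR and 5 bLR arrays of postnatal day 14. The 11 arrays had medians between 4.846 and 4.859 on the log2 scale, and their pairwise correlations across probe sets lay between 0.981 and 0.987. Correlations averaged 0.983 within bHR, 0.985 within bLR and 0.984 between the lines. Probe sets are not independent replicates, so these correlations describe the arrays only.

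Whether the values belong to the genes named in the rows could not be established, so every gene name below stands for the probe set labelled with it. Xist, the RNA that coats the inactive X chromosome in females, was at 6.49 ± 0.084 in bHR (SD, n = 6) and 6.58 ± 0.12 in bLR (SD, n = 5), although all rats were male. The mean level of Xist was at percentile 94.25 among the tested probe sets. The sex check had no measured Y-linked gene. Levels of different probe sets depend on probe affinity and background as well as on the transcript. This percentile and those that follow therefore describe the table and decide nothing about single genes.

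Members of broadly expressed families (361 probe sets, such as proteasome, translation factor and respiratory chain genes) had a mean level percentile of 48.95 ± 28.8 (SD), and members of families best known from other organs (300 probe sets) one of 50.7 ± 29.9. The difference was -1.75 percentile points (95% interval -6.27 to 2.79), and -1.19 against a wider set of 442 that also holds genes of brain. Choice by symbol prefix left the other sets mixed too. The 300 hold Il16, a planned marker of dentate granule neurons, and the 361 hold Calml4, one of choroid plexus and ependyma. Single genes abundant in brain, among them Mbp, Nrgn and Snap25, averaged the 64.4th percentile over 14 probe sets, against 49.7 for 24 genes of other organs, a difference of 14.7 points (95% interval -0.259 to 29.6). Of the 40 planned lists, the mitochondrial respiratory chain list had a median percentile of 71.3 over 45 probe sets, above 99.9% of random lists of its size (permutation, adjusted p = 0.088), and general excitatory neuron markers had the highest median, 78.2 over 10 (adjusted p = 0.697, permutation). The lowest medians were 27.6 for CA1 pyramidal neurons and 31.6 for dentate granule neurons, over 7 probe sets each. Blood cell markers had a median of 70.5 over 10 (adjusted p = 0.697 for all 3, permutation). Levels of the 54 control sets showed no grouping by transcript. Of their variance 9.10% lay between the 12 transcripts, against 20.7% on average for shuffled names (permutation test, p = 0.956). Changes between arrays do not depend on affinity in this way, but noise lowers the correlation of dim sets. Control sets of the same transcript, after subtraction of the group means, correlated at 0.072 on average over 105 pairs, against 0.016 for shuffled names (permutation test, p = 0.0484, 11 arrays).

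**Figure D1:**
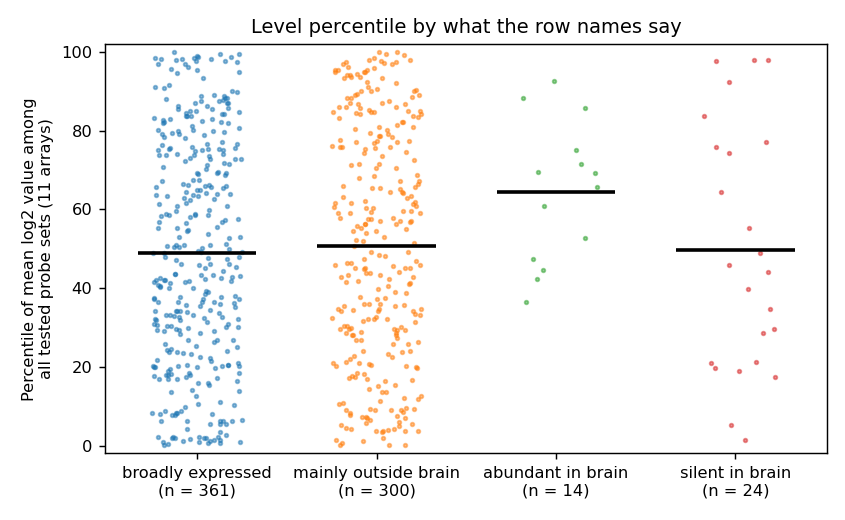
Percentile of the mean log2 value over 11 arrays for each probe set (points) of 4 sets defined by row names, with the set's mean as a black line. The broadly expressed families and the families of other organs both cover the whole range, with means of 48.95 and 50.7, and levels also depend on each set's probes.

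No probe set differed between the lines past the threshold. With limma, 0 of 9962 probe sets passed an adjusted p of 0.05 and 0 passed 0.10, and the smallest adjusted p was 0.302. At an unadjusted p under 0.05 there were 480 probe sets, 237 higher and 243 lower in bHR, against 498.1 given by chance. The median absolute difference was 0.050 and the largest 0.63 on the log2 scale. The 95% interval of the difference excluded 0.5 in either direction for 99.02% of probe sets, with a median reach of 0.15 to each side. The groups did not overlap for 48 probe sets (0.482%), and chance gives 0.433%.

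**Figure D2:**
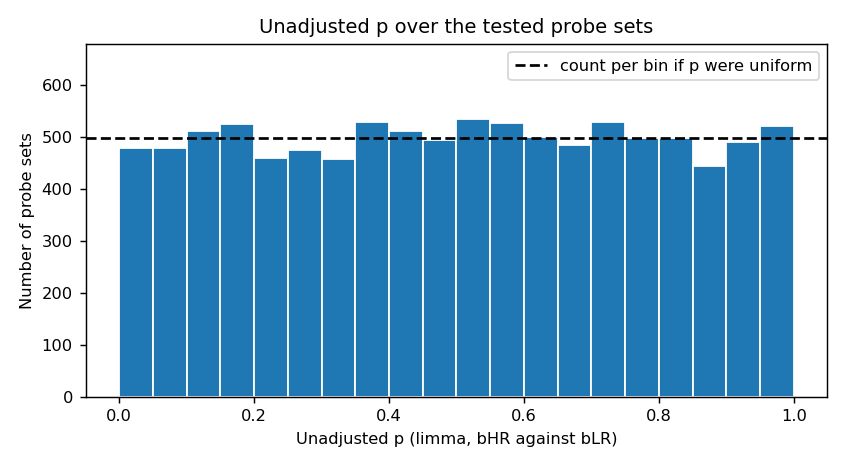
Number of probe sets (y axis) by unadjusted p of the limma comparison (x axis), in steps of 0.05, with the count that uniform p-values would give as a dashed line at 498.1. The first step holds 480 probe sets and lies below the line.

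The largest difference was at the probe set labelled Top2b, a DNA topoisomerase present in postmitotic cells. It was at 5.27 ± 0.32 in bHR (SD, n = 6) and 4.64 ± 0.17 in bLR (SD, n = 5), a difference of 0.63 (SE 0.13, limma adjusted p = 0.542). Prf1, the perforin of cytotoxic lymphocytes, had the smallest adjusted p, 0.302 by limma, with a difference of 0.37 (SE 0.063). Hars1, a histidyl-tRNA synthetase, was at 4.47 ± 0.16 in bHR and 4.001 ± 0.17 in bLR, a difference of 0.47. All 6 bHR arrays lay above the bLR mean for these 3 probe sets. The other differences among the 10 higher were 0.41 for Tle2, 0.34 for Cpne5, 0.28 for Traf4, Lhfpl2 and Dus1l, 0.24 for Ilf2 and 0.21 for Smu1. With the failed array included, the differences were 0.23 for Top2b, 0.88 for Hars1, -0.058 for Cpne5, 0.090 for Traf4 and 0.18 for Tle2. No limma adjusted p among these 10 was below 0.302.

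Among the 10 with lower values in bHR, Stx18, a syntaxin of the endoplasmic reticulum, had the largest difference. It was at 4.93 ± 0.32 in bHR (SD, n = 6) and 5.41 ± 0.16 in bLR (SD, n = 5), a difference of -0.48 (SE 0.13, limma adjusted p = 0.992), with 5 of 6 bHR arrays below the bLR mean. S1pr3, a sphingosine 1-phosphate receptor, differed by -0.31 (SE 0.064) and had the smallest adjusted p of this direction, 0.542 by limma. Tiparp, an ADP-ribosyltransferase induced through the aryl hydrocarbon receptor, differed by -0.30. Laptm5, a lysosomal protein of blood and microglial cells, differed by -0.36, and Rab2a, a small GTPase of vesicle traffic, by -0.35. The remaining differences were -0.31 for Nup133, -0.28 for Zfp689, -0.27 for Asf1b, -0.26 for Gpx1 and -0.22 for Gja4. With the failed array included, the differences were -0.060 for Nup133, -0.24 for Laptm5 and -0.40 for Gpx1. The groups did not overlap for 13 of these 20 probe sets, which were picked for small p.

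**Figure D3:**
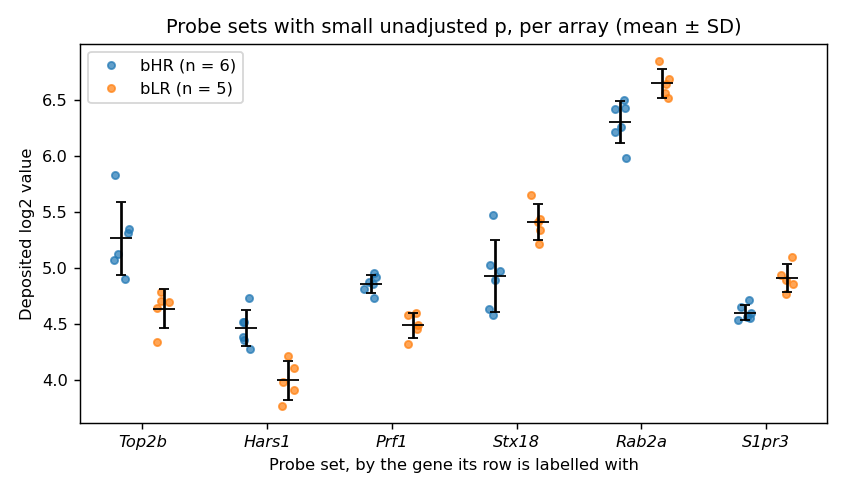
Deposited log2 values (y axis) of the 6 bHR arrays (blue) and 5 bLR arrays (orange) for 6 probe sets with small unadjusted p, with mean and SD in black. The lines overlap at Stx18 and are apart at the others, and no probe set passed the adjusted threshold.

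Candidate genes of these lines were examined next. The list held 26 measured genes and is not independent of these arrays. None passed over all probe sets, and 0 passed when adjusted over the list alone (smallest adjusted p 0.837, limma). Only Drd2, a dopamine receptor, was under an unadjusted p of 0.05, with a difference of -0.16 (SD 0.0997 in bHR, n = 6, and 0.107 in bLR, n = 5). Bmp4, a growth factor of the bone morphogenetic protein family, was at 5.57 ± 0.16 in bHR and 5.65 ± 0.085 in bLR, a difference of -0.079 (95% interval -0.24 to 0.085). Ucp2, a mitochondrial uncoupling protein, differed by 0.18 (95% interval -0.038 to 0.40). The complement gene C1qa differed by 0.039 (95% interval -0.096 to 0.17) and the thyrotropin-releasing hormone receptor Trhr by 0.036 (95% interval -0.070 to 0.14). Fgf2, a fibroblast growth factor, differed by -0.038 (95% interval -0.27 to 0.20) and the ion transport regulator Fxyd7 by 0.0034 (95% interval -0.23 to 0.24). The levels of these probe sets were low, at percentiles 0.080 for Fgf2 and 8.25 for Fxyd7, and whether they were detected could not be judged. With the failed array included, the differences were 0.54 for Ucp2, 0.14 for C1qa, 0.13 for Trhr, -0.11 for Fgf2 and -0.16 for Fxyd7. The direction of Fgf2 and Fxyd7 changed when single arrays were left out. Over the settings other than the failed array, Bmp4 ranged from -0.11 to -0.029, Ucp2 from 0.10 to 0.27, C1qa from 0.017 to 0.086, Fxyd7 from -0.087 to 0.089 and Fgf2 from -0.18 (with the oligodendrocyte mean as covariate) to 0.016. The groups overlapped for all 6 of these candidates.

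Of the 40 lists, 0 passed camera at its preset correlation (smallest adjusted p 0.844), and 0 passed with an estimated correlation, with fry in either form or with the exact permutation test. At an unadjusted p under 0.05, camera and directional fry had 0 lists, the mixed form of fry had 2 (striatum and endothelial cells, adjusted p = 0.827 each in limma) and the exact permutation test had 1. No list had a member past an adjusted p of 0.05, over all probe sets or adjusted over the list alone (smallest 0.0519, limma). The lists covered 800 probe sets, of which 41 had an unadjusted p under 0.05. Medians of the lists lay between -0.045 and 0.032. Where values do not belong to their row names, a list is an arbitrary set of probe sets. Its result, here and below, then says nothing about the named pathway or cell type. Median, mean and camera direction differed in sign for 10 lists: dentate granule neurons, CA3 and CA2 pyramidal neurons, interneurons, thalamus and habenula, neuropeptides and their receptors, cholesterol and fatty acid synthesis, the FGF system, synaptic vesicle and release machinery, complement and innate immunity, and the candidate genes.

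Neuronal markers had medians near 0. CA1 pyramidal neuron markers had the lowest median, -0.045 over 7 probe sets, 6 of them with negative differences, such as -0.16 for Gpr161. The medians were -0.016 for general excitatory neurons, -0.012 for dentate granule neurons, -0.0098 for CA3 and CA2 neurons, -0.0051 for interneurons and -0.0048 for immature neurons. Examples among dentate granule neuron markers were 0.12 for Dsp, -0.080 for Tdo2 and -0.091 for the calcium-binding protein Calb1. The RNA-binding protein Elavl4, a CA3 and CA2 marker, differed by 0.13. Among interneuron markers, Pvalb differed by -0.075, Kit by 0.081 and Sst by -0.070. Sox11, a transcription factor of young neurons, differed by -0.17. Markers of tissue bordering the hippocampus had medians of -0.011 for neocortex and subiculum, -0.0054 for thalamus and habenula and 0.030 for striatum.

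Glial and vascular markers were alike in this. Oligodendrocyte markers had a median of -0.015 over 22 probe sets, with differences of -0.17 for Gjb1, -0.12 for Mobp and -0.087 for Mbp, the last 2 encoding myelin proteins, and 0.17 for the receptor Gpr37. Oligodendrocyte precursor markers had a median of 0.022 over 7 probe sets, with 0.21 for Tnr and 0.064 for Cspg4. The median was 0.0086 for astrocytes and radial glia, with 0.13 for the water channel Aqp4, and -0.026 for microglia, with -0.36 for Laptm5, 0.079 for C1qb and -0.077 for Csf1r. Endothelial markers had the highest median, 0.032 over 13 probe sets, with 0.26 for the glucose transporter Slc2a1 and 0.28 for Eng. The medians were -0.021 for pericytes, smooth muscle and meningeal cells, -0.041 for choroid plexus and ependyma, with 9 of 11 differences negative, such as -0.099 for Enpp2 and -0.10 for Folr1, and 0.079 for Ttr, and -0.013 for blood cells.

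Growth and signalling lists did not pass either. The thyroid hormone and retinoid list had 18 of 23 positive differences, a median of 0.027 and the smallest camera p, 0.844 after adjustment, with -0.17 for Rxrg and 0.14 for Aldh1a2. In the BMP and TGF-beta list 23 of 31 differences were negative, with a median of -0.037, yet Acvr1 and Inhbb differed by 0.16 and 0.18. The medians were -0.010 for the FGF system, with 0.17 for Spred1 and -0.18 for Fgf1, 0.0081 for neurotrophins and growth factors, with 0.23 for Ngfr, -0.028 for cell cycle and DNA replication, with -0.16 for Mcm7, 0.0064 for the glucocorticoid and stress axis, with 0.14 for Hsd11b2, -0.018 for immediate early genes, with 0.23 for Egr4, and 0.0048 for extracellular matrix.

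Among synaptic lists, the GABA list had a median of 0.0035 and a difference of 0.37 for Gabra3, a receptor subunit, and was the list with an unadjusted exact permutation p of 0.0498 (adjusted p = 0.861, exact permutation). The medians were -0.016 for glutamate receptors, with -0.15 for Grm5, -0.011 for monoamine receptors and transporters, with -0.17 for Htr1b and 0.14 for Maob, and -0.00078 for neuropeptides, with 0.12 for Penk. They were -0.037 for cholinergic and endocannabinoid signalling, with 0.22 for Slc18a3 and -0.18 for Chrm4, 0.010 for synaptic vesicle and release machinery, with -0.13 for Syn1, 5.2e-05 for postsynaptic scaffold and plasticity kinases, and -0.023 for potassium channels, with 0.22 for Kcnip1 and -0.29 for Kcnq3.

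Metabolic and stress lists gave medians of -0.0041 for the mitochondrial respiratory chain, with -0.24 for Cox4i1 and 0.21 for Uqcrc2, and -0.015 for uncoupling and antioxidant genes, which include Gpx1. Cholesterol and fatty acid synthesis had a median of -0.0069, with 0.29 for Mvd, an enzyme of the mevalonate pathway. The medians were 0.022 for heat shock and the unfolded protein response, 0.014 for complement, MHC and innate immunity, with -0.16 for Irf1, -0.013 for the circadian clock, with -0.11 for Per1, and -0.012 for the candidate genes.

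The bLR array described as failed was set beside the 11 others without a test. Its correlations with them across probe sets were 0.539 to 0.547. Its value lay outside the range of the 11 for 80.4% of probe sets, where chance gives 16.7%, and each of the 11 lay outside the range of the remaining arrays for 14.98% to 22.03%. Its median was 4.88 and its SD over probe sets 1.12, slightly above those of the others (4.846 to 4.859 and 1.098 to 1.104). RMA equalises the distribution of values across arrays, so the small size of these gaps says nothing about the quality of the array.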

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

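The test of what the number of arrays allowed was chosen after the result had been seen. The counts over other splits of the arrays, and the test of covariation among control sets, were written before their results were seen.

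Whether the values belong to the genes named in the rows stays open. Levels of different probe sets cannot decide it, since they depend on probe affinity and background, which the table does not give. The levels of the control sets showed no grouping by transcript (9.10% of variance, against 20.7% for shuffled names, permutation test, p = 0.956). Values that do not belong to their row names would give this, but so could differing affinity of the sets of 1 transcript. The 18 hybridization control sets (bioB, bioC, bioD and cre) had a median level of 4.61. The median was 4.56 for the 39 other control sets and 4.85 for all tested probe sets. Hybridization controls thus did not stand above the tested probe sets, though their levels also depend on their probes. Covariation across arrays does not compare levels between sets, though noise in dim sets weakens it. Values that do not belong to their row names would leave control sets of 1 transcript no more correlated than sets with shuffled names. Their mean correlation was 0.0723, just above the 95th percentile of 0.0717 for shuffled names, and far below the 0.3 set in advance as evidence that names hold, so the test is undecided. The control sets are named in the deposited table itself, without a gene table. Of the probe sets that both symbol tables named, 95.55% had the same symbol, which argues against a wrong gene table there. Exchanged values and weak hybridization cannot be told apart here, and no biological explanation was tested.

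The absence of differences between the lines was weighed next. The number of arrays is argued against as a reason for missing log2 differences of 0.5 in the deposited values at most probe sets. The interval excluded such differences for 99.02% of probe sets, while smaller differences stay open. Of 100 splits of the 11 arrays drawn, the real one included, 46 gave at least the 480 probe sets at an unadjusted p under 0.05 (highest other 770), so chance cannot be excluded for that count. For the 0 probe sets, 0 lists and 0 candidate genes past the threshold the splits decide nothing, since all 100 reach a count of 0 by definition (highest other 1, 1 and 0). For the remaining probe sets differences of 0.5 stay open, among them Top2b (95% interval 0.35 to 0.91), Hars1 (0.28 to 0.66) and Stx18 (-0.75 to -0.20). The intervals excluded a difference of 1 in either direction for 100% of probe sets. Differences of any size stay open for genes whose values do not belong to their row names. All these intervals concern deposited values. How closely the values follow transcript amounts was not tested, so larger differences in transcript amount are not excluded.

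Single arrays stood apart from their group at 4 of 56 places examined, against 2.8 given by chance. These were Tle2 in bHR replicate 3, at 3.64 against 3.90 to 4.05 in the other 5 arrays, and Ilf2 in bLR replicate 1, at 3.51 against 3.64 to 3.67 in the other 4. In bLR replicate 4 the median of all probe sets was 4.859, against 4.853 to 4.855, and the SD was 1.098, against 1.102 to 1.103. The failed array, which the comparison did not use, lay outside the range of the others at 80.42% of probe sets and correlated with them at no more than 0.5474.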

How the results depend on the processing

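All alternatives were fixed before the data were examined. Under every one that was run, limma called 0 probe sets and 0 candidate genes and camera 0 lists; the smallest adjusted p for a probe set ranged from 0.142 (dimmest 30% left out) to 0.966 (oligodendrocyte mean as covariate). The 480 probe sets at an unadjusted p under 0.05 became 170 with the failed array included, whose values differed from the mean of the 11 with an SD of 1.06; with array weights, where that array had a weight of 0.022, they were 489. Leaving out each array in turn gave 429 to 520. Of the log2 differences of named genes, 576 kept their direction and side of the threshold and 14 changed sign; the cause was not tested. By over 1.5 times, 13 of the 26 named differences moved with the failed array included; under the other settings none of the 20 with the smallest p did, and 5 of the 6 candidates did. With the failed array included, Cpne5 was at -0.058 and Fxyd7 at -0.16. Fxyd7 was at -0.018 with the failed array and array weights and at -0.015 with array weights on the 11 arrays. Over the arrays left out in turn, Fxyd7 ranged from -0.087 to 0.089 and Fgf2 from -0.097 to 0.016.

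The labels do not say that sample numbers pair the arrays. Deviations from the group means correlated between same-numbered arrays at 0.027 to 0.091 in 5 pairs, none over 0.1. As a hint from the data, 4 of 5 bHR arrays correlated best with their own number, and no other of the 120 pairings had a higher mean (exact 1-sided permutation p = 0.0083, the smallest possible). With the number as a replicate block, 0 probe sets, 0 lists and 0 candidates passed (smallest adjusted p 0.372), 518 probe sets had an unadjusted p under 0.05, and Fxyd7 was at -0.028. Averaging the probe sets of a gene, or taking the second brightest, gave no value because each gene has 1 probe set. Signal over background could not be judged.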

Other observations

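The first principal component of the 11 arrays held 13.6% of the variance and the second 12.6%, against at most 10.98% for the first in 20 shufflings of each probe set's values.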
